A study of Mus musculus with 6 samples.

How the data were processed

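The T cell receptor β chain (TCR-β) repertoire was sequenced from total RNA of C57BL/6 mice that carried a tumor in each hindlimb. Per the labels' protocols, RNA was converted to double-stranded cDNA, an adaptor was ligated to its 5′ end, the TCR-β sequences were amplified in successive PCRs with an adaptor primer and constant region primers, and the libraries were sequenced on a MiSeq with paired reads of 300 bp. No molecular identifiers are named in the labels, so a read is not an independent molecule.

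Each of the 6 deposited files lists, per the file headers, a TRBV gene, a TRBJ gene, the amino acid sequence of complementarity-determining region 3 (CDR3), a read count and a percentage. The counts are whole reads as deposited by the authors, with no normalization. The deposited percent values are read shares rounded to 2 decimals. They matched the reads divided by the total of sequences without a stop or frame mark to within 0.00499 percentage points in every library, whereas division by all reads left differences of up to 0.832 percentage points. The authors' percent values therefore count only unmarked sequences as the whole, and the same total was used here. The aligner, the germline reference, the method of V and J assignment and any handling of sequencing errors are not given in the sources used here.

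A clonotype was defined as a combination of TRBV gene, TRBJ gene and CDR3 amino acid sequence with no stop (*) or frame (.) mark, called productive. The files give no nucleotide sequences, so this is the finest definition they allow. The libraries held between 44472 and 145211 reads, of which 42320 to 135599 were productive. Marked reads made up 4.45% to 6.62% of a library. A single read was worth between 0.000737% and 0.00236% of a library's productive reads, and a count of 0 allows a share of up to 3 reads, which is 0.00221% in spleen 2 and 0.00709% in distant tumor 2. Intervals for the share of a clonotype in a library are Wilson 95% confidence intervals. Intervals and floors cover counting error only, since PCR without molecular identifiers can multiply a molecule into many reads.

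Because richness and entropy grow with depth, diversity and overlap were computed after drawing 42320 productive reads, the total of the smallest library, from each library without replacement. Values are means over 100 seeded draws. The measures were the number of clonotypes, Shannon entropy in natural-log units, the inverse Simpson index, evenness (Shannon entropy divided by the natural log of the number of clonotypes) and the share of reads in the most abundant clonotype and in the 10 and 100 most abundant. Overlap between libraries was measured with the Morisita-Horn index, the number of shared clonotypes and the share of reads in shared clonotypes for all 15 pairs of libraries. Group values were compared by exact permutation tests, two-sided. With 2 libraries against 2 the smallest p is 0.333 and with 4 tumors against 2 spleens it is 0.0667, so neither comparison can pass a threshold of 0.05. Reads per clonotype in the treated and the distant tumor with the same replicate number were compared with Fisher's exact test, two-sided, over clonotypes with at least 10 reads in both libraries together, with Benjamini-Hochberg adjustment. That test compares 2 libraries and not the conditions.

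Reads per TRBV and TRBJ gene were tested with edgeR's quasi-likelihood test, with low-count filtering and scaling by the library total, in a fit of all 6 libraries as 3 groups that leaves 3 residual degrees of freedom, and Benjamini-Hochberg adjustment over the genes of each kind. Positions of genes are those of the GENCODE M21 annotation (GRCm38), to which all 35 gene symbols in the files matched, 23 TRBV and 12 TRBJ. The reference the authors assigned genes with is not given in the sources used here. TRBV12-1 and TRBV12-2, and the members of the TRBV13 family, are close relatives, so reads could be split between them.

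The groups come from the sample titles, with 2 libraries each of treated tumor, distant tumor and spleen. The series describes 2 mice and the titles number the libraries of each group 1 and 2, which was taken to mean that libraries with the same number come from the same mouse. As a check, the deviations of TRBV usage (log2 shares) from the group means were correlated over 21 genes between libraries with the same number. The correlation was 0.539 for treated and distant tumor, 0.129 for treated tumor and spleen and 0.0759 for distant tumor and spleen. Clonotype sharing by number is given with the overlap results. P-values of the permutation and edgeR tests measure the spread between these libraries, and the treated and distant tumors of a mouse are not independent. Those of Fisher's tests and of the sign test rest on reads, clonotypes or sequences and hold no spread between libraries.

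The rules for named items and the tests described above were fixed before the data were examined, while the tests of the closing parts and some alternatives were chosen afterwards, as said there. Named clonotypes are the 5 most abundant of each tumor library, the 3 most abundant of each spleen library, and for each replicate number the 3 with the highest smaller share in the treated and the distant tumor. Named genes are TRBV and TRBJ genes past the threshold or, with fewer than 5 of them, the 5 TRBV genes with the largest absolute log2 fold change, given as values. Lists fixed in advance were the β chains of the transgenic receptors OT-I and pmel-1, V genes of OT-I type, of invariant natural killer T (NKT) type and of mucosal-associated invariant T (MAIT) type, the TRBV12 and TRBV13 families (the TRBV12 list has the same 2 genes as the OT-I type list), V pseudogenes, and the TRBJ1 and TRBJ2 clusters.

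The alternatives were CDR3 amino acids alone, leaving out clonotypes with 1 read, merging variants that differ by 1 residue from a clonotype at least 100 times as abundant, no rarefaction, other overlap measures, other read minimums, other normalizations, DESeq2, no low-count filter, every clonotype counted once, all rearrangements, the replicate number as a block, and leaving out replicates. Added after seeing the data were a CDR3 that starts with C and ends with F or W, leaving out the 10 most abundant clonotypes of each library, leaving out each library in turn, and leaving out 1 widely shared clonotype.

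On simulated TRBV counts for treated against distant tumor, drawn for 22 genes, the edgeR test recovered 5.33% of 2-fold and 39.0% of 4-fold changes and called 0.37% and 4.58% of unchanged genes. On simulated reads for treated tumor 1 against distant tumor 1, with 2212 and 2008 clonotypes tested, Fisher's test recovered 18.0% of 2-fold and 89.5% of 4-fold changes among 200 clonotypes. It called 0.199% and 7.19% of the others, part of which may come from the shift in shares that large changes force on all other clonotypes. The simulated reads were independent draws, which PCR reads are not, so these rates are not the error rates of the test on the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.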

Results

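The TCR-β repertoire was measured in 6 libraries from C57BL/6 mice. MO4 cells, a B16F10 melanoma line that expresses ovalbumin (OVA), were injected under the skin of both hindlimbs on day 0, with 100000 cells per site. Interferon-α-producing myeloid cells derived from induced pluripotent stem cells (IFN-α-iPSC-pMC, 1000000 cells) were then injected next to the right tumor 5 times, on days 5 to 7 and on days 12 and 13, and RNA was extracted on day 14. The injected right tumor is called the treated tumor and the left tumor, which received no cells, the distant tumor. Spleen is the third tissue. Each tissue has 2 libraries, numbered 1 and 2. The series gives as its purpose the characterization of tumor-infiltrating T cells, and the design sets the T cells of an injected tumor beside those of a tumor at a distance and of the spleen.

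Treated tumor 1 held 83171 productive reads in 12761 clonotypes, distant tumor 1 held 82142 in 11201 and spleen 1 held 96907 in 64726. Treated tumor 2 held 56057 productive reads in 7539 clonotypes, distant tumor 2 held 42320 in 10347 and spleen 2 held 135599 in 92233. Between 72.0% and 82.6% of the clonotypes of a library were seen in 1 read. These clonotypes carried 10.2% to 17.6% of the reads in the tumors and 48.7% and 50.04% in the spleens.

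Tumor reads were concentrated in a small number of clonotypes, and spleen reads were not. At an equal depth of 42320 reads, the tumors held 7741 ± 1870.2 clonotypes (SD, n = 4) and the spleens 34763 ± 1446 (SD, n = 2). The 10 most abundant clonotypes took 24.3% ± 9.93 (SD, n = 4) of the reads in tumors and 1.07% ± 0.0760 (SD, n = 2) in spleens, and the 100 most abundant took 47.1% ± 7.56 and 3.11% ± 0.474. Shannon entropy was 6.76 ± 0.617 in tumors and 10.3 ± 0.0662 in spleens, the inverse Simpson index was 141 ± 92.7 and 18699 ± 1539, and evenness was 0.756 ± 0.0552 and 0.988 ± 0.00240. For these 6 measures every tumor library lay on the same side of both spleen libraries, and the exact permutation test (two-sided, 4 against 2) gave 0.0667, the smallest p that its 15 splits allow. The most abundant clonotype took between 3.06% and 18.5% of the reads of a tumor and 0.243% and 0.302% of those of a spleen (exact permutation p = 0.267, two-sided, n = 4 and n = 2). The 4 tumors come from the same animals in pairs, so they are not 4 independent samples. Equal depth evens out reads and not T cells. The number of T cells behind each library is not known here, so its part in these differences cannot be told apart from that of the tissue.

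**Figure D1:**
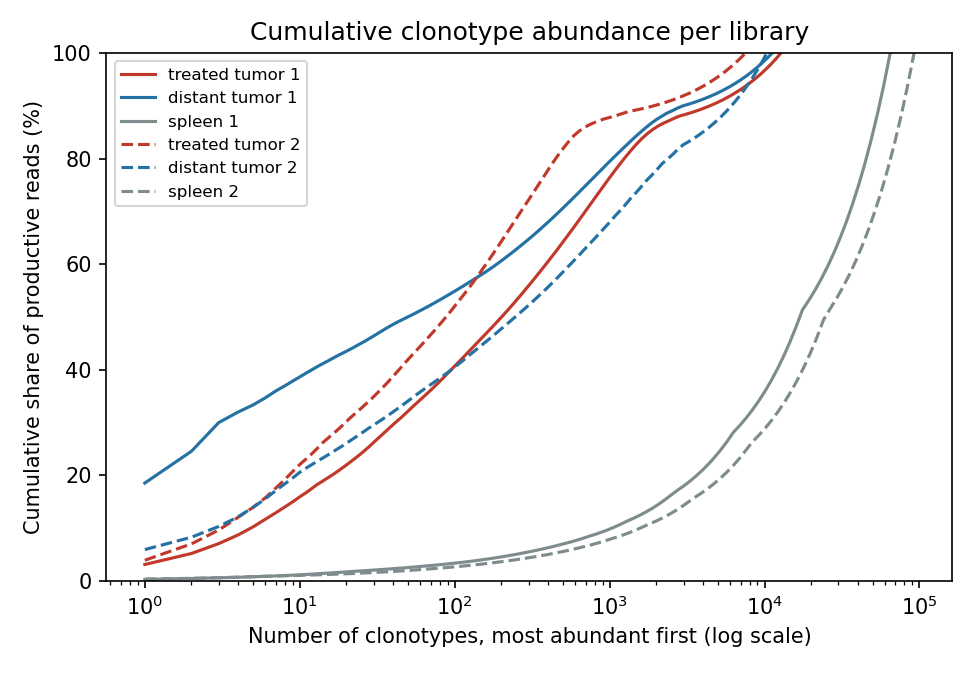
Cumulative share of productive reads (%, vertical axis) against the number of clonotypes counted from the most abundant (log scale, horizontal axis), with 1 line per library and no rarefaction. The 4 tumor lines rise early, with 3.07% to 18.5% of reads in the most abundant clonotype, while both spleen lines lie far below them at every number up to the 100 most abundant.

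Of 7 diversity measures, only the share of the most abundant clonotype differed between treated and distant tumors in the same direction in both replicate numbers. At equal depth the treated tumors held 6828 ± 1194 clonotypes and the distant tumors 8653 ± 2396 (SD, n = 2 each), and Shannon entropy was 6.80 ± 0.528 and 6.71 ± 0.925. In replicate number 1 the treated tumor was more diverse than the distant tumor, with an entropy 1.11 higher, and in number 2 it was less diverse, with a difference of -0.941. The inverse Simpson index was 250.1 and 23.5 in treated and distant tumor 1, and 141 and 148 in treated and distant tumor 2. The share of the most abundant clonotype was lower in the treated tumor in both numbers, at 3.06% against 18.5% and 3.87% against 5.89%. The exact permutation test (two-sided, 2 against 2) gave 0.333 for this share, the smallest p it allows, and 0.667 or 1 for the other 6 measures (n = 2 each). The differences in the other 6 measures had opposite signs in the 2 replicate numbers. With clonotypes of 1 read left out, the number of clonotypes and the share of the top 10 were also lower, and the inverse Simpson index higher, in the treated tumor of both numbers (exact permutation p = 0.333 each, two-sided, n = 2 each).

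The clonotypes at the head of each list are those with the most reads, which need not be those with the most T cells. In distant tumor 1 the TRBV12-1/TRBJ1-2 clonotype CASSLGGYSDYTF alone took 15201 reads, or 18.5% (Wilson 95% interval 18.2% to 18.8%). It had 190 reads in treated tumor 1, or 0.228% (0.198% to 0.263%), so its share was 81.0 times higher in the distant tumor, and it had 0 reads in spleen 1 and 1 read in spleen 2. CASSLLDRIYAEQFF (TRBV29/TRBJ2-1) took 6.02% of distant tumor 1 (5.86% to 6.19%) with 0 reads in treated tumor 1, which makes it at least 1670.3-fold higher against a floor of 3 reads. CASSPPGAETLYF (TRBV5/TRBJ2-3, 2.00%) and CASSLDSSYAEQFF (TRBV3/TRBJ2-1, 1.35%) followed in distant tumor 1 and reached 0.424% and 0.103% of treated tumor 1.

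Treated tumor 1 was led by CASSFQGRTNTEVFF (TRBV15/TRBJ1-1) with 3.07% of its reads (2.95% to 3.19%), against 0.112% in distant tumor 1. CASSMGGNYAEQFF (TRBV19/TRBJ2-1, 2.09%) and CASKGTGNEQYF (TRBV13-1/TRBJ2-7, 1.53%) had 0 reads in distant tumor 1, so they were at least 572-fold and at least 419-fold higher in the treated tumor. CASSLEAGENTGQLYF (TRBV12-2/TRBJ2-2) took 1.88% of treated tumor 1 and 0.461% of distant tumor 1. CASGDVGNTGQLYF (TRBV13-2/TRBJ2-2) took 1.64% and 0.0158%, and it was found in the treated tumor of number 2 as well, with 0.480% there and 0.0165% in distant tumor 2. The ratio of treated to distant tumor for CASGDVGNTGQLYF was 103.7 in number 1 and 29.0 in number 2.

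In replicate number 2 both tumors were led by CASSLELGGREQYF (TRBV16/TRBJ2-7), with 2172 reads or 3.87% of treated tumor 2 (3.72% to 4.04%) and 2494 reads or 5.89% of distant tumor 2 (5.67% to 6.12%). The same clonotype had rank 3 in distant tumor 1, with 4461 reads or 5.43% (5.28% to 5.59%). It had 0 reads in treated tumor 1, which allows a share of up to 0.00361%, and 6 and 5 reads in spleens 1 and 2. Treated tumor 2 also held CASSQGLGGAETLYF (TRBV5/TRBJ2-3, 3.10%) and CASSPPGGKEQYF (TRBV5/TRBJ2-7, 2.40%), both with 0 reads in distant tumor 2, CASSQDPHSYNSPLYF (TRBV5/TRBJ1-6, 2.63%) with 0.0638% in distant tumor 2, and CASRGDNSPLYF (TRBV13-1/TRBJ1-6, 1.89%) with 0.161%. Distant tumor 2 held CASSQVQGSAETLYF (TRBV5/TRBJ2-3, 2.35%), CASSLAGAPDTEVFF (TRBV16/TRBJ1-1, 2.04%) and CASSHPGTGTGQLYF (TRBV5/TRBJ2-2, 1.83%), all with 0 reads in treated tumor 2, and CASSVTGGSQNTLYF (TRBV13-1/TRBJ2-4, 1.80%) with 0.257% in treated tumor 2.

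Some clonotypes were abundant in both tumors of a number. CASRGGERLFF (TRBV19/TRBJ1-4) took 0.412% of treated tumor 1 and 0.388% of distant tumor 1, values that did not differ (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.466), and it had 0 reads in the other 4 libraries. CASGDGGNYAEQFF (TRBV13-2/TRBJ2-1) took 1.35% and 1.26% of treated and distant tumor 2 (Fisher's exact test, adjusted p = 0.211) and 0.108% of spleen 2. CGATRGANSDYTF (TRBV20/TRBJ1-2) took 1.04% and 1.56% of the same tumors (Fisher's exact test, adjusted p = 3.91e-12) and 0.115% of spleen 2, where it had rank 3. The leading spleen clonotypes were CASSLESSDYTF (TRBV15/TRBJ1-2) with 0.303% and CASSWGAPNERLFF (TRBV14/TRBJ1-4) with 0.144% in spleen 2. In spleen 1 they were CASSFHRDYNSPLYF (TRBV14/TRBJ1-6) with 0.244%, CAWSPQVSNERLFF (TRBV31/TRBJ1-4) with 0.172% and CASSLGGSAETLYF (TRBV17/TRBJ2-3) with 0.128%. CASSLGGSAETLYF also took 1.35% of distant tumor 1 and 0.114% of treated tumor 1.

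Most tested clonotypes differed in share between the treated and the distant library of the same number. Most were found in only 1 of them, and for those the minimum of 10 reads fixed the call. In replicate number 1, 2257 clonotypes had at least 10 reads in both tumors together, and 1223 had a higher share in the treated tumor and 938 in the distant tumor, while 96 did not pass the threshold (Fisher's exact test, Benjamini-Hochberg adjustment). In number 2, 1113 clonotypes were tested, 537 were higher in the treated tumor, 509 in the distant tumor and 67 passed in neither direction. The balance depended on the read minimum. In number 1, 1562 were higher in the treated and 1593 in the distant tumor with at least 5 reads, and 240 and 109 with at least 50. In number 2, 610 were higher in the treated and 1218 in the distant tumor with at least 5 reads, and 210 and 69 with at least 50. With the minimum of 10 reads, only 360 of the 2257 and 240 of the 1113 tested clonotypes were detected in both tumors. In number 1, 1058 were found in the treated tumor alone and 839 in the distant tumor alone. In number 2 these were 407 and 466. A clonotype with at least 10 reads, all in 1 library, passes Fisher's test at these depths. The counts of calls thus largely reflect detection in 1 library and say little about clonotypes present in both. These tests take reads as independent, which PCR reads are not, and they compare 2 libraries.

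**Figure D2:**
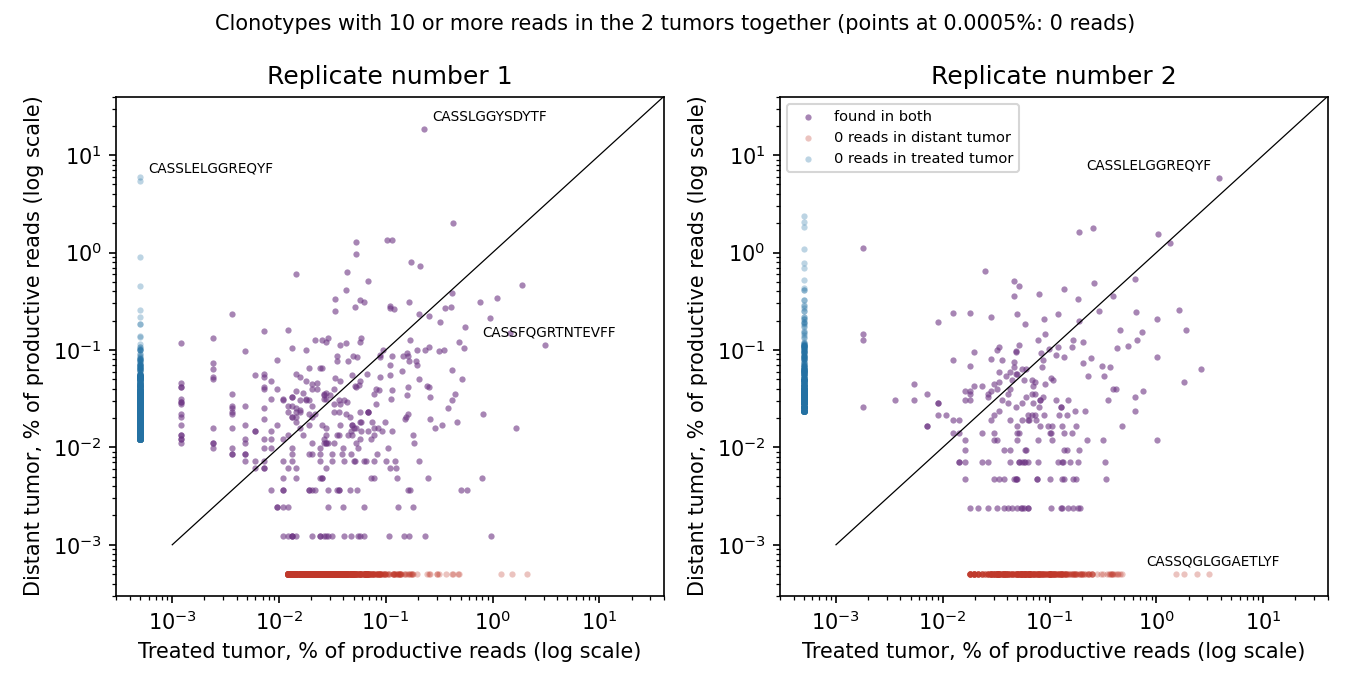
Share of productive reads in the treated tumor (%, log scale, horizontal axis) and in the distant tumor (%, log scale, vertical axis) for each clonotype with at least 10 reads in both together, 1 panel per replicate number. Clonotypes with 0 reads in a tumor are drawn at 0.0005%, and the diagonal marks equal shares; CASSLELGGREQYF lies on the edge of panel 1, with 0 reads in treated tumor 1, and at the upper right of panel 2.

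The treated and the distant tumor of the same number shared more clonotypes than tumors of different numbers. At equal depth the treated and distant tumors of the same number shared 430.0 and 391 clonotypes (numbers 1 and 2), which carried 37.9% of the reads of treated tumor 1, 45.0% of distant tumor 1, 43.3% of treated tumor 2 and 28.4% of distant tumor 2. The 4 pairs of tumors of different numbers shared 116 ± 32.6 clonotypes (SD, n = 4 pairs), which carried 5.51% to 15.2% of the reads. The next counts are at full depth, where the tumors of number 1 had more productive reads (83171 and 82142) than those of number 2 (56057 and 42320). Of the 100 most abundant clonotypes of treated tumor 1, 67 were found in distant tumor 1 and 22 in distant tumor 2, and of those of treated tumor 2, 54 were found in distant tumor 2 and 9 in distant tumor 1. Of the 100 most abundant clonotypes of distant tumor 1, 72 were found in treated tumor 1 and 14 in treated tumor 2, and of those of distant tumor 2, 46 were found in treated tumor 2 and 15 in treated tumor 1.

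The Morisita-Horn index, which weights abundant clonotypes, was 0.0422 for treated and distant tumor 1 and 0.439 for treated and distant tumor 2. Between tumors of different numbers it was 0.0636 ± 0.0553 (SD, n = 4 pairs), and the pair of distant tumors reached 0.131, above the value for the tumors of number 1. The order was the other way on measures that weight abundant clonotypes less, with a Bhattacharyya overlap of 0.0866 for the pair of distant tumors and 0.237 for the tumors of number 1, and Jaccard indices of 0.00910 and 0.0303. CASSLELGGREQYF carried much of this index in pairs where both tumors held it. Treated tumor 1 had 0 reads of it. With this clonotype, the index of treated tumor 1 at full depth was 0.0422 with distant tumor 1, 0.0227 with treated tumor 2 and 0.0144 with distant tumor 2. Without this clonotype, an alternative chosen after seeing the data, the index at full depth was 0.171 for the tumors of number 2 and 0.0430 for those of number 1. For tumors of different numbers it was then 0.0260 (treated 1 and treated 2), 0.0214 (treated 1 and distant 2), 0.00145 (distant 1 and treated 2) and 0.00140 (the pair of distant tumors). With 2 mice no test of this difference can reach 0.05.

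Tumor clonotypes were found in the spleen with the same number more often than in the other spleen. Counts of the 100 most abundant clonotypes of a tumor are at full depth, with 96907 productive reads in spleen 1 and 135599 in spleen 2. Of these clonotypes, 49 (treated tumor 1), 57 (distant tumor 1), 52 (treated tumor 2) and 71 (distant tumor 2) were detected in the spleen with the same number, and 32, 26, 11 and 21 in the other spleen. The Morisita-Horn index between tumor and spleen was 0.0149 ± 0.00923 (SD, n = 4 pairs) within a number and 0.00383 ± 0.00277 (SD, n = 4 pairs) across numbers. The spleens shared 1848 clonotypes with each other at equal depth, with an index of 0.0725, and 3622 with an index of 0.175 when clonotypes were defined by CDR3 amino acids alone. The rank 1 clonotypes of treated tumor 1 and distant tumor 1, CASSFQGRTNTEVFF and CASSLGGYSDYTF, had 6 and 0 reads in spleen 1, and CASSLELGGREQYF, which led both tumors of number 2, had 5 in spleen 2.

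Usage of TRBV genes was compared next, since a preferred V gene can mark a shared specificity. No TRBV gene passed the threshold between treated and distant tumors (0 of 23, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 each), with 3 genes at an unadjusted p under 0.05 and 2 genes called lower by DESeq2. The 2 called by DESeq2 were TRBV12-1 (chromosome 6, 41113550 to 41114067) and TRBV17 (chromosome 6, 41163062 to 41163556). TRBV12-1 took 2.39% ± 1.34 of the reads of treated tumors and 13.9% ± 14.9 of those of distant tumors (SD, n = 2 each), with a log2 fold change of -2.54 (SE 0.94, edgeR adjusted p = 0.260). Its share was 24.4% in distant tumor 1, where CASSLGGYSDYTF alone took 18.5%, and 3.34% in distant tumor 2. Without distant tumor 2 the log2 fold change of TRBV12-1 was -3.35 (edgeR adjusted p = 5.7e-06), and without distant tumor 1 it was -0.48 (edgeR adjusted p = 0.705). TRBV12-1 passed the threshold with clonotypes counted once (log2 fold change -1.37, edgeR adjusted p = 0.0249) and not without the 10 most abundant clonotypes of each library (-1.01, adjusted p = 0.0664). In that last fit 1 other TRBV gene was called lower in treated tumors (edgeR adjusted p = 0.0310). Counted once, TRBV12-1 held 11.6% and 4.504% of the clonotypes of distant tumors 1 and 2, and 3.99% and 2.22% in treated tumors. Merging variants of 1 residue raised the most abundant clonotype of distant tumor 1, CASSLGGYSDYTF, from 18.5% to 19.8% of reads at equal depth. Usage was not fitted with variants merged, so the part of such variants in the call with clonotypes counted once was not tested. TRBV17 took 1.29% ± 0.169 of treated tumors and 2.97% ± 0.334 of distant tumors, with a log2 fold change of -1.21 (SE 0.28, edgeR adjusted p = 0.115). TRBV19 (chromosome 6, 41178375 to 41179048) had 5.64% ± 3.76 and 2.64% ± 0.260 (log2 fold change 1.10, SE 0.50, edgeR adjusted p = 0.313). TRBV24 (chromosome 6, 41218091 to 41218557), annotated as a pseudogene, had 9 and 61 reads in treated tumors 1 and 2 and 11 and 4 in distant tumors 1 and 2. Its log2 fold change was 2.32 (SE 1.14, edgeR adjusted p = 0.313), and without treated tumor 2 it was -0.13. TRBV24 passed the threshold when treated tumor 1 was left out (log2 fold change 3.19, edgeR adjusted p = 0.00920). TRBV21 (chromosome 6, 41202550 to 41203044) had at most 2 reads in any tumor library, too few for a fold change between them.

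**Figure D3:**
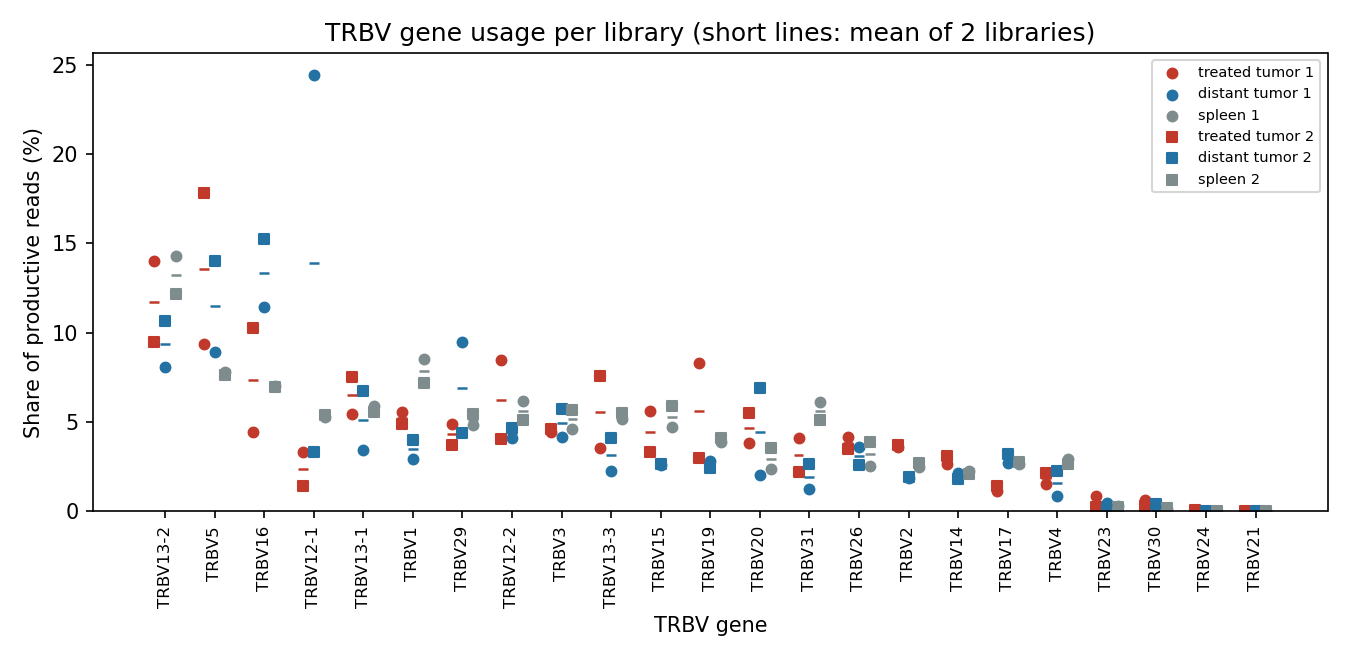
Share of productive reads (%, vertical axis) of each of 23 TRBV genes (horizontal axis, ordered by mean share) in the 6 libraries, with points for libraries and short lines for the mean of 2 libraries. Distant tumor 1 stands at 24.4% for TRBV12-1, against 1.44% to 5.37% in the other libraries.

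Between tumors and spleens, 0 of 23 TRBV genes passed the threshold of the edgeR test, 4 genes had an unadjusted p under 0.05, and DESeq2 called 1 gene higher (TRBV30) and 1 lower (TRBV21). TRBV31 (chromosome 6, 41557691 to 41558452), the only TRBV gene of the locus on the opposite strand, took 2.55% ± 1.196 of tumor reads (SD, n = 4) and 5.63% ± 0.712 of spleen reads (SD, n = 2), with a log2 fold change of -1.19 (SE 0.41, edgeR adjusted p = 0.185). TRBV1 (chromosome 6, 40891229 to 40891885) took 4.35% ± 1.12 and 7.83% ± 0.948 (log2 fold change -0.88, SE 0.27, edgeR adjusted p = 0.185), TRBV4 (chromosome 6, 41059394 to 41059886) 1.71% ± 0.654 and 2.79% ± 0.180 (log2 fold change -0.71, SE 0.42, edgeR adjusted p = 0.400), and TRBV30 (chromosome 6, 41281376 to 41281990) 0.402% ± 0.156 and 0.174% ± 0.0521 (log2 fold change 1.18, SE 0.43, edgeR adjusted p = 0.185). TRBV21 had 23 and 26 reads in the spleens and 0 to 2 in the tumors. Leaving out distant tumor 2 put TRBV31 (edgeR adjusted p = 0.00676) and TRBV4 (0.0283) past the threshold, leaving out treated tumor 1 put TRBV21 past it (0.0347), and leaving out treated tumor 2 put TRBV21 (0.0242) and TRBV24 (0.0393) past it.

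Of 12 TRBJ genes, TRBJ1-2 (chromosome 6, 41534001 to 41534048) was lower in treated than in distant tumors, at 4.78% ± 0.541 against 15.2% ± 12.6 of reads (SD, n = 2 each; log2 fold change -1.67, SE 0.51, edgeR adjusted p = 0.0290). Its share was 24.1% in distant tumor 1, which holds the TRBJ1-2 clonotype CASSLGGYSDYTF, and 6.31% in distant tumor 2. The call was lost with the replicate number as a block (log2 fold change -1.50, edgeR adjusted p = 0.265), with clonotypes counted once (-0.76, adjusted p = 0.362) and without the 10 most abundant clonotypes of each library (-0.34, adjusted p = 0.732, chosen after seeing the data). It was also lost without distant tumor 1 (log2 fold change -0.40, edgeR adjusted p = 0.874), treated tumor 1 (-1.56, 0.123), treated tumor 2 (-1.79, 0.0673), spleen 1 (-1.67, 0.189) or spleen 2 (-1.67, 0.205), so in the last 4 fits the fold change stayed about as large. Of the 6 single-library omissions, only that of distant tumor 2 kept the call (-2.33, adjusted p = 0.00196). Between tumors and spleens 0 of 12 TRBJ genes passed the edgeR threshold, 1 had an unadjusted p under 0.05 (TRBJ1-5) and DESeq2 called 0.

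The OT-I receptor recognizes a peptide of OVA, the antigen that MO4 cells carry, and the pmel-1 receptor recognizes the melanocyte protein gp100. The OT-I β chain (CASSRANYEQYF with TRBV12-1) had 0 reads in all 6 libraries, which allows a share of up to 0.00361% and 0.00535% in treated tumors 1 and 2, and 0.00365% and 0.00709% in distant tumors 1 and 2. The pmel-1 β chain (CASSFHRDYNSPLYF with TRBV14) had reads in all 6 libraries. It took 0.635% of treated tumor 2 (Wilson 95% interval 0.573% to 0.704%), 0.244% of spleen 1, where it had rank 1, and 0.234% of distant tumor 1. It took 0.0331% of distant tumor 2 and 0.00811% of spleen 2, and it had 3 reads in treated tumor 1. The β chain alone does not give the specificity of a receptor.

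V genes of OT-I type, TRBV12-1 and TRBV12-2, took 8.66% ± 4.43 of treated, 18.3% ± 14.5 of distant tumor and 11.0% ± 0.702 of spleen reads (SD, n = 2 each). Their share was 28.6% in distant tumor 1 and 7.98% in distant tumor 2, against 11.8% and 5.52% in treated tumors 1 and 2. It was thus higher in the distant tumor of both numbers, although the distant mean rested largely on distant tumor 1. The 5 V genes of invariant NKT type (TRBV1, TRBV13-1, TRBV13-2, TRBV13-3 and TRBV29) took 33.4% ± 0.216, 28.0% ± 2.60 and 37.3% ± 1.95. The 3 of MAIT type (TRBV13-2, TRBV13-3 and TRBV19) took 23.0% ± 4.11, 15.2% ± 2.84 and 22.6% ± 1.09, and the 3 of the TRBV13 family 23.8% ± 1.11, 17.6% ± 5.42 and 24.3% ± 1.45. The NKT and MAIT lists name V genes that ordinary T cells use as well, and no α chains were measured. The TRBJ1 cluster took 31.2% ± 3.73, 37.9% ± 8.50 and 31.7% ± 0.359, and the TRBJ2 cluster the rest. In edgeR with Benjamini-Hochberg adjustment over all genes of the same kind, 0 genes of the V lists passed in either comparison, and 0 passed when adjusted over the list alone. In the TRBJ1 cluster 1 gene (TRBJ1-2, treated against distant) passed in both ways of adjustment. The 12 listed V pseudogenes (TRBV6 to TRBV11, TRBV12-3, TRBV18, TRBV22, TRBV25, TRBV27 and TRBV28) had 0 reads in every library; TRBV24, also annotated as a pseudogene, is not in that list and had reads.

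CDR3 length weighted by reads did not separate the tissues. The mean length over reads was 13.9 ± 0.00153 residues in treated tumors and 13.8 ± 0.105 in distant tumors (SD, n = 2 each; exact permutation p = 1, two-sided). It was 13.9 ± 0.0681 in all tumors (SD, n = 4) and 13.8 ± 0.0284 in spleens (SD, n = 2; exact permutation p = 0.800, two-sided). In distant tumor 1, 34.4% of reads had a CDR3 of 13 residues, the length of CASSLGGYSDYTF, against 15.7% in treated tumor 1 and 20.3% in spleen 1. With clonotypes counted once the mean lengths were 13.94 and 13.99 in treated tumors 1 and 2, 13.906 and 13.91 in distant tumors and 13.89 and 13.87 in spleens, in that order without overlap. The difference was then 0.0586 residues for treated minus distant tumors (exact permutation p = 0.333, two-sided, n = 2 each) and 0.0552 for tumors minus spleens (exact permutation p = 0.133, two-sided, n = 4 and n = 2).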

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

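All tests in this part were chosen after the pattern was seen, and for each except that of productive parents of marked sequences the criterion was also written after its result was known.

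Sequences with a stop or frame mark are outside every comparison above, and in the tumors a few of them held many reads. The 10 most abundant marked sequences took 12.6% of the marked reads in treated tumor 1, 20.3% in distant tumor 1, 27.7% in treated tumor 2 and 14.1% in distant tumor 2, against 1.09% and 0.603% in spleens 1 and 2. Errors in reads of abundant productive clonotypes would leave marked sequences beside a parent with the same TRBV, TRBJ and first 6 residues and at least 20 times the reads, but at most 23.5% of the marked reads in sequences of 10 or more reads had such a parent in any tumor. Non-productive rearrangements that expanded T cells carry and transcribe are a candidate explanation. Of 133 such sequences without a parent, 10 recurred in the other tumor of the same number. In the corresponding tumor of the other number 2 recurred (one-sided exact sign test, p = 0.0193), so the test rests on 12 sequences. Counted per library, 74 and 32 sequences without a parent came from treated and distant tumor 1, and 20 and 11 from those of number 2. The tumors of number 1 had more reads (87784 and 85987) than those of number 2 (58667 and 44472). Depth alone thus favours recurrence within number 1, and the test cannot tell it from such rearrangements. The form of this test was changed 2 times after a result had been seen, and both earlier forms had given a smaller p.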

How the results depend on the processing

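Leaving out single libraries or the 10 most abundant clonotypes, requiring a CDR3 from C to F or W, and leaving out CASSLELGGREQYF were chosen after seeing the data. The 7 measures of tumors against spleens kept their direction under every alternative run. In the chosen setting, differences between treated and distant tumor within single replicate numbers ranged from -4363 to 714 clonotypes, -0.941 to 1.11 (Shannon entropy), -6.81 to 227 (inverse Simpson), -0.0580 to 0.117 (evenness), -22.8 to 1.47 (share of the top 10, in percentage points) and -14.3 to 11.6 (top 100). Without clonotypes of 1 read, clonotypes, inverse Simpson and top 10 kept 1 sign in both numbers, and with variants merged inverse Simpson did. Mean CDR3 length differences, weighted by reads, ranged from -0.0185 to 0.127 residues (treated minus distant) and from -0.0352 to 0.0801 (tumors minus spleen), and without clonotypes of 1 read from -0.0287 to 0.136 and from 0.0152 to 0.161. The MAIT type V share difference of 7.81 percentage points ranged from 2.89 to 12.7 by number and was 3.64 with clonotypes counted once, where that of the NKT type fell from 5.34 to 1.52. With the replicate number as a block, the number of TRBJ genes called between treated and distant tumors went from 1 to 0, and no other call changed; the paired differences in diversity cannot give an exact p under 0.5. TRBJ calls for treated against distant tumors were 0 with clonotypes counted once and without the 10 most abundant clonotypes, 2 with TMM (trimmed mean of M-values) normalization, and 0 to 3 when a library was left out. TRBJ calls for tumors against spleens were 1 without the 10 most abundant clonotypes, 2 with clonotypes counted once and 0 to 2 when a library was left out. TRBV calls for treated against distant tumors were 2 with DESeq2, 1 with clonotypes counted once, 1 without the 10 most abundant clonotypes and 0 to 1 when a library was left out. TRBV calls for tumors against spleens were 2 with DESeq2, 2 with clonotypes counted once, 1 with all rearrangements, 1 without the 10 most abundant clonotypes and 0 to 2 when a library was left out. The log2 fold change of TRBV24 ranged from -0.29 to 3.37 over left-out libraries and numbers, and was -0.13 without treated tumor 2. At full depth, shared clonotypes of treated and distant tumor fell from a mean of 513 to 154 with at least 10 reads in both libraries. The tumor and spleen overlap of the same number was 0.0249 without clonotypes of 1 read. On other scales it was 0.0721 (Bhattacharyya overlap), and that of tumors of different numbers was 0.00748 (Jaccard index). Clonotypes differing between treated and distant tumor were 349 in number 1 and 279 in number 2 with a minimum of 50 reads, and 1828 in number 2 with a minimum of 5, since fewer or more clonotypes were then tested. When 1 residue could differ, sequences near the OT-I chain took a mean of 0.00125% of spleen reads. These were 1 read in spleen 1 and 2 reads in spleen 2, and the exact chain had 0. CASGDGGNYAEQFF had a log2 ratio of treated to distant tumor 2 of 0.11, and -0.00441 without clonotypes of 1 read, where the totals change. For the other changes the cause was not tested. Among named clonotypes, 122 of 124 alternative values kept direction and side of the threshold. Among named genes 148 of 173 did, while 15 gained a call, 8 lost it and 2 changed direction. The 173 include fits without a whole replicate number, which gave no p and were counted by direction alone. They also include the fit without the low-count filter, which tested the same genes as the chosen setting and could not differ. The share that kept its side of the threshold is therefore partly fixed by construction. Fits without a whole replicate number have no residual degrees of freedom and gave values only, and where a group is left with 1 library, that library is assumed to vary like the others. Nucleotide clonotypes were not run, because the files hold amino acids. A count of 0 leaves room for shares of up to 0.00221% to 0.00709% of a library.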

Other observations

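All tests in this part were chosen after seeing the data. For misassigned reads and carry-over, the criteria were also written after the results were known. Related receptors were counted among the tumor clonotypes of all 4 tumors together, without a test per replicate number. Merging variants of 1 residue left 3205 tumor clonotypes with at least 10 reads, and 72 combinations of a TRBV gene and the first 7 CDR3 residues occurred in at least 5 of them. Of these, 18 were more frequent among tumor than among spleen clonotypes (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted over the 72). In 100 random draws of as many spleen clonotypes the mean number past the threshold was 0.950 and the highest 6, from a mean of 41.8 stems tested, fewer than the 72 in tumors. The TRBV5 stem CASSPPG began 8 of 3205 tumor and 66 of 150747 spleen clonotypes (odds ratio 5.71, adjusted p = 0.00224). It took 0.946% and 2.98% of the reads of treated and distant tumor 1 and 4.68% and 0.567% of those of treated and distant tumor 2, against 0.0475% and 0.0406% in spleens 1 and 2, so it was higher in 4 of 4 tumors than in either spleen. Only 3 of the 18 stems met this, and stems were picked for being frequent in tumors. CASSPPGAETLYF and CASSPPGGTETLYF led it in distant tumor 1, and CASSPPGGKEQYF, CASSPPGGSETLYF and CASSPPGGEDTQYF in treated tumor 2. The TRBV1 stem CTCSAER began 12 tumor and 91 spleen clonotypes (odds ratio 6.22, adjusted p = 0.000121) but took 0.169% of distant tumor 1 against 0.196% of spleen 1, and the TRBV5 stem CASSQVQ 6 and 15 (odds ratio 18.8, adjusted p = 0.000121). CASSQVQ had 0 reads in treated tumor 2, and the TRBV14 stem CASSLTG had 5 clonotypes of at least 10 reads in each tumor of number 1 and 0 in each of number 2. Tumor clonotypes were chosen by a read minimum and spleen clonotypes were not, so the sets differ in abundance as well as in tissue.

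Of the 175 clonotypes at 0.1% or more of a tumor of replicate number 1, 8 also reached that level in a tumor of number 2. Besides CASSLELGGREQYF, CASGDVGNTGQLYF and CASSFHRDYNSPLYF, they were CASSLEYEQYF, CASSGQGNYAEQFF, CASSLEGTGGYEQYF, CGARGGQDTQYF and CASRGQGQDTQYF. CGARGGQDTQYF (TRBV20/TRBJ2-5) took 1.11% and 0.342% of treated and distant tumor 1 and 0.430% of distant tumor 2, with 0 reads in treated tumor 2.

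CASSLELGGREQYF was abundant in tumors of both replicate numbers and rare in both spleens, with a lowest ratio of tumor to spleen of the same number of 877 in the 3 tumors that held it, a value that describes the pattern and does not test it. Reads assigned to the wrong library would carry other abundant clonotypes along. Of the 20 other most abundant clonotypes of the donor library at most 1 reached 0.1 of the ratio of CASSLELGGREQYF, in 4 directions between distant tumor 1 and the tumors of number 2, which argues against them. Open are carry-over from outside the 6 libraries, which was not tested for this clonotype, and a β chain selected in the tumors of both mice, which may follow from a shared antigen. No antigen was tested, and treated tumor 1 held 0 reads.

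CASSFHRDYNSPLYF, the pmel-1 β chain, was found in all 6 libraries, and the question is whether these reads come from T cells of these mice. Reads assigned to the wrong library between treated tumor 2 and spleen 1 or distant tumor 1 are argued against, since in the 4 directions at most 1 of the 20 other most abundant clonotypes of the donor reached 0.1 of its ratio. In the other directions from these 3 libraries up to 16 of 20 did, with 13 from spleen 1 into distant tumor 1, so its reads there and the low counts of treated tumor 1, distant tumor 2 and spleen 2 could be misassigned or shared by T cells of a mouse. Material from outside the 6 libraries, such as cells or cDNA of transgenic mice, could add a sequence with few similar neighbours. It had 2 neighbours of 1 residue in spleen 2, against a median of 6 and a range of 2 to 18 for the 18 other clonotypes found in all libraries, and 2 of those 18 had as few, which decides neither for carry-over nor for a public receptor of these mice.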
